A study of Mus musculus with 12 samples.

How the data were processed

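RNA from 12 mouse libraries, 3 each of epidermis and papilloma given camphor white oil (CWO) or vehicle, was sequenced by the submitters. Per the labels, epidermis was separated from skin with ammonium thiocyanate, and the 3 samples per treatment with the best RNA integrity were sequenced. According to the submitters' processing notes, reads were made with bcl2fastq 1.8.4, aligned to mm9 with TopHat2 2.0.4, quantified with Cufflinks 2.0.2, and compared with DESeq. The deposited per-library files give FPKM per gene with its interval and a Cufflinks status. The authors' comparison tables give a mean signal per group as normalised counts, with a fold change as a ratio, its log2 value, a p-value and an adjusted p-value. Per the file headers these are the mean signal of each group, the ratio (fold), the log2 ratio and the p-value. The authors' epidermis table lists 176 genes with a highest adjusted p of 0.00544, and their papilloma table lists 23284. The epidermis cut is tighter than the 0.05 used here, so a gene absent from it may still lie under 0.05 there. Positions are mm9 and 1-based as listed in the deposited files, and no position from another build was used.

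Values with a Cufflinks status other than OK were set to missing, a choice made after the files were seen, since 11 genes around Krt6a had too many reads for Cufflinks in 4 papilloma libraries and were listed at 0. The FPKM of 248 symbols with more than 1 row were summed, giving 23235 symbols. Fragment numbers were recovered from FPKM and the Cufflinks interval, taken as 2 standard deviations of a fragment count. They gave 11.1 to 24.6 M (mega) fragments per library, which limits what can be seen in genes of low level. Of recovered values under 500 fragments, 67.9% to 69.2% per library were whole within 0.02. Their ratio to the authors' mean counts in papilloma had a median of 0.98, and 90.8% of 13044 genes lay within 1.25-fold.

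The main test was limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(FPKM + 1) with the deposited FPKM not rescaled. Genes needed an FPKM of at least 1 in at least 3 of the libraries fitted, with at least 2 values per group, and short non-coding genes were left out, since a polyA library does not measure them. The threshold was a Benjamini-Hochberg adjusted p under 0.05, two-sided. Comparisons were CWO against vehicle in each tissue, the difference of these effects in a fit of all 12 libraries, and papilloma against epidermis under vehicle. The tests, gene lists, gene panel and naming rule were chosen before the data were examined. Epidermis replicates are samples, and the labels do not say how replicate numbers of the 2 treatments relate.

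The 43 gene lists cover immune cells, antigen presentation, cytokines, stress responses, proliferation, keratinocyte states, lipid synthesis, skin appendages and other cell types. They were tested with camera at a preset correlation of 0.01 where at least 5 members were measured, which left 3 lists untested in each tissue's treatment comparison. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance in one direction, were alternatives. In epidermis 26 of 40 lists did not pass camera, in papilloma 29 of 40, in the difference 27 of 42 and between tissues 20 of 42. Some genes belong to more than 1 list, such as Stfa3, Il1f6, Scd3 and Slpi. Genes were named by 3 rules: those with the largest changes in each direction among called genes whose groups do not overlap, unnamed gene models and pseudogenes left out; the members with the smallest p in lists that passed; and a fixed panel. Where fewer than 3 genes passed in a direction, the 3 with the smallest p were named as not passing. Of the genes that these rules pick, 1 is not reported here. For genes below the filter an exact permutation test, two-sided, was used.

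The pipeline was tested on simulated data, with known changes put into each gene's own spread. Changed genes were drawn from those with a mean log2 level above 3, and genes varied independently. At each size 50 genes were changed, together with the cholesterol synthesis list, which eases the adjusted threshold. The shares recovered therefore do not carry over to genes of low level or to data with few changed genes. At log2 changes of 0.5, 1 and 2 it recovered 22%, 84% and 98% of changed genes in epidermis, 60%, 88% and 96% in papilloma and 10%, 66% and 98% for the difference. Between tissues it recovered 30%, 88% and 96%. Alternatives fixed in advance were pseudocounts of 0.1 and 3, other filters, median-ratio scaling, quantile normalization, other limma settings, short genes kept, a 2-fold minimum, replicate blocks, all 12 libraries in one fit, and each library left out. Added after the data were seen were values used whatever their status, limma-voom on recovered fragments, the muscle list mean as a covariate, and both muscle-rich epidermis vehicle libraries left out. The last leaves 1 library in that group, an exception to the 2 values per group, which is assumed to vary like the other groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.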

Results

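Gene expression was measured by polyA RNA sequencing in 12 libraries from FVB/NJ mice, with 3 libraries in each of 4 groups. Camphor white oil (CWO), an essential oil distilled from the camphor tree, was applied at 20%, and acetone was the vehicle. Epidermis was taken 24 h after 400 µL of CWO or vehicle. Papillomas, which are pre-malignant skin tumours, were raised with 400 nmol of the carcinogen DMBA and repeated 10 nmol doses of the tumour promoter TPA. They were then given CWO or vehicle for 6 weeks, and 4 tumours of similar size were pooled from each of 3 mice per group. The files list FPKM for 23235 gene symbols. The sequenced fragments recovered from them numbered 13.0, 11.1 and 24.6 M (mega) in epidermis given vehicle and 17.9, 18.3 and 18.0 M in epidermis given CWO. In papillomas they numbered 15.6, 19.5 and 19.0 M with vehicle and 20.4, 17.1 and 16.9 M with CWO. Between 11874 and 12489 genes per library reached an FPKM of 1. All positions are on the mm9 mouse genome. Levels are mean FPKM ± SD over 3 libraries, and log2 fold changes are on the log2(FPKM + 1) scale, which understates changes in genes of low level.

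The first comparison asked which genes a single application of CWO changed in normal epidermis within 24 h. With unnamed gene models and pseudogenes left out, the 6 largest rises among called genes whose groups did not overlap were as follows. Sprr2a2, a small proline-rich precursor of the cornified envelope, rose from 15.6 ± 2.91 to 189 ± 80.0 FPKM (n = 3; log2 fold change 3.44, SE 0.308, adjusted p = 0.00311). Stfa3, a stefin that inhibits cysteine proteases (chromosome 16, 36450623 to 36455478), rose from 27.6 ± 7.16 to 204 ± 50.5 FPKM (log2 fold change 2.84, SE 0.220, adjusted p = 0.00221). Sprr2h, Stfa1 and Sprr2d rose by log2 fold changes of 3.05, 3.04 and 2.43. Sprr2a2, Sprr2h and Stfa1 are absent from the authors' list for epidermis, which holds no adjusted p above 0.00544. Sprr2a2 is listed at 2 places whose FPKM were summed, so its level depends on how reads shared between copies were assigned. Chi3l1, a secreted chitinase-like protein of inflamed tissue (chromosome 1, 136078981 to 136086608), rose by 2.59.

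Among genes that fell in epidermis, Hamp2 and Hamp, which encode hepcidin peptides, had log2 fold changes of -2.96 and -3.08, and Hamp2 (chromosome 7, 31707391 to 31709200) went from 1393 ± 160 to 208 ± 149 FPKM. Scd3, a stearoyl-CoA desaturase of sebaceous glands, had a log2 fold change of -1.95, Cartpt, a neuropeptide precursor, of -2.40, and Gng13, a G protein gamma subunit, of -2.13. The ribosomal protein gene Rpl34 was called at -3.06, with FPKM of 172, 214 and 143 under vehicle and 30.4, 10.6 and 24.2 under CWO. It is absent from the authors' list for epidermis, which has the tighter cut given above. Rpl34-ps1, a pseudogene listed at the same place and picked out after its values were seen, went the other way (log2 fold change 5.89, adjusted p = 0.038). The FPKM of the 2 summed to 172, 214 and 170 under vehicle and 209, 196 and 210 under CWO, so the call reflects how reads were assigned between them.

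**Figure D1:**
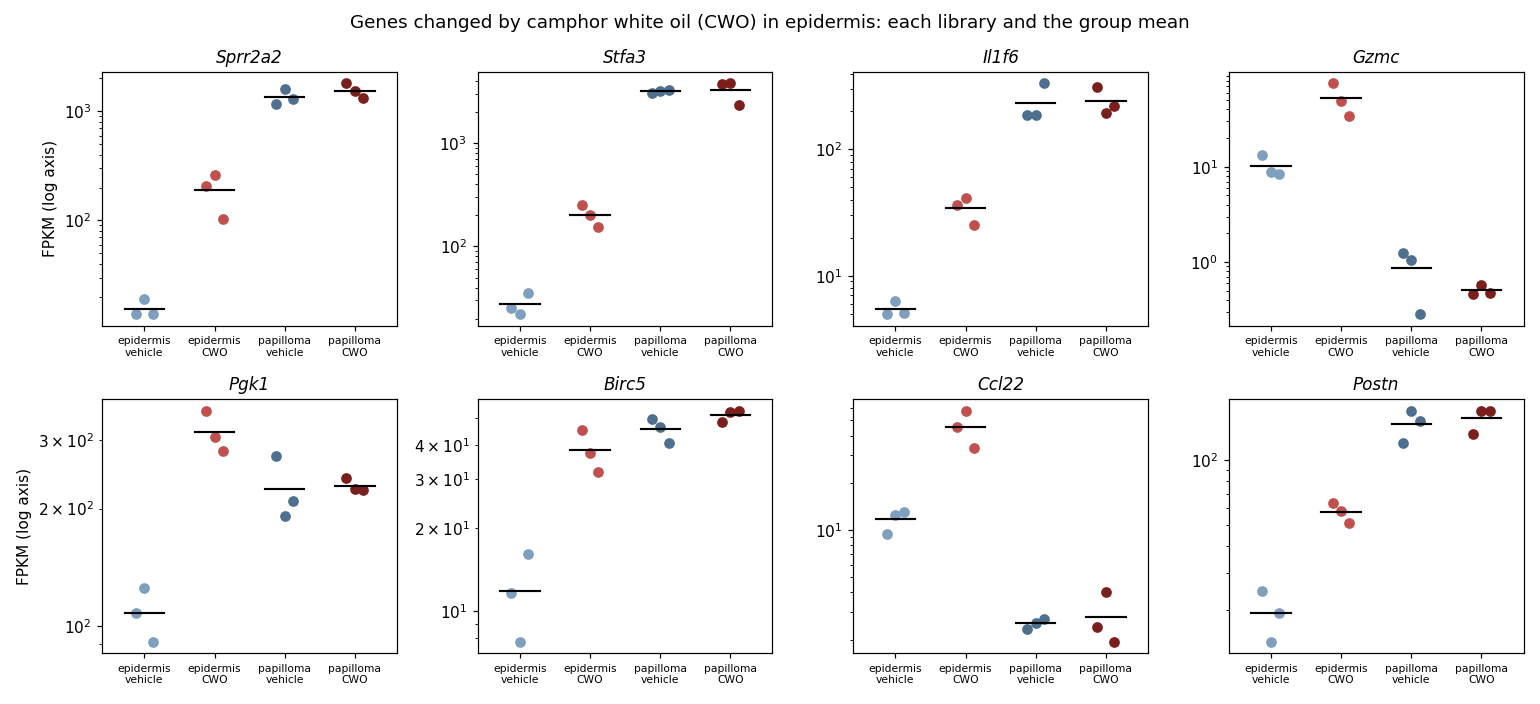
FPKM (log axis, y) of 8 genes changed by CWO in epidermis, by tissue and treatment (x). Points are libraries (3 per group) and lines are group means. The mean of Stfa3 is 27.6 in epidermis given vehicle, 204 in epidermis given CWO and 3210 in papillomas given vehicle.

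Cell cycle genes rose as a group. Of 30 measured members 17 rose, none fell and 13 did not pass, 29 rose adjusted over the list alone, and the median log2 fold change was 1.13 (camera adjusted p = 4.8e-26, adjusted p = 0.416 with an estimated correlation). Birc5 (survivin) went from 11.8 ± 4.19 to 38.2 ± 6.80 FPKM (log2 fold change 1.65), and Aurkb, a mitotic kinase, and Ccna2 (cyclin) had log2 fold changes of 1.51 and 1.43. In the list of metallothioneins and hypoxia genes 7 of 16 rose and 9 did not pass, and 12 rose adjusted over the list alone (median 0.852; camera adjusted p = 3.45e-13, adjusted p = 0.152 with an estimated correlation). Its risers were hypoxia-responsive genes such as Pgk1, a glycolytic kinase that went from 108 ± 16.9 to 314 ± 38.5 FPKM (log2 fold change 1.54). Egln3, an oxygen-sensing prolyl hydroxylase, rose by 1.62 and Ndrg1 by 0.90. Stress keratins and alarmins had 6 risers among 17 measured and 11 that did not pass, with 11 rising adjusted over the list alone (median 1.85; camera adjusted p = 7.72e-12, adjusted p = 0.227 with an estimated correlation). They included Stfa3, Stfa1 and Il1f6, an epithelial cytokine of the interleukin family, which went from 5.46 ± 0.761 to 34.4 ± 8.32 FPKM (log2 fold change 2.43).

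Cholesterol synthesis genes also shifted upward: 3 of 19 rose and 16 did not pass, and 11 rose adjusted over the list alone (median 0.456; camera adjusted p = 1.98e-07, adjusted p = 0.448 with an estimated correlation). The risers included Cyp51 (0.74), a sterol demethylase, and Idi1 (0.79), an isoprenoid isomerase. In the cornified envelope list 6 of 23 rose and 17 did not pass, with 10 rising adjusted over the list alone. Its median was 0.128 and its mean 0.777, since the risers were mainly Sprr genes such as Sprr2f (log2 fold change 2.13) (camera adjusted p = 0.000974, adjusted p = 0.592 with an estimated correlation). The sebaceous gland list held 1 riser, the fatty acid elongase Elovl3 (1.78), and 1 gene that fell, Scd3, among 16, with 14 not passing. Adjusted over the list alone, 6 rose and 2 fell (median 0.262; camera adjusted p = 0.0215, adjusted p = 0.448 with an estimated correlation). Krt79 and Dgat2l6 of that list had log2 fold changes of 0.64 and 0.69 and did not pass. Immediate early genes had 1 riser, Ier3 (0.63), among 22, and 21 did not pass, with 1 rising and 1 falling adjusted over the list alone. That list's median was 0.265 (camera adjusted p = 0.0199, adjusted p = 0.592 with an estimated correlation); Egr2 and Dusp1 had 0.40 and 0.77 and did not pass.

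Several lists of immune genes passed upward. Of 11 Langerhans and dendritic cell genes 3 rose and 8 did not pass, and 7 rose adjusted over the list alone (median 0.721; camera adjusted p = 4.55e-07, adjusted p = 0.416 with an estimated correlation). Ccl22, a chemokine made by dendritic cells, went from 11.7 ± 1.93 to 45.4 ± 12.1 FPKM (log2 fold change 1.85), and Ccr7, the receptor that guides their migration, and Cd83, a maturation marker, rose by 1.01 and 0.77. Inflammatory cytokines and chemokines had 2 risers among 10, Il1f6 and the chemokine Ccl20 (2.13), and 8 that did not pass. Adjusted over the list alone 6 rose (median 0.608; camera adjusted p = 5.81e-07, adjusted p = 0.227 with an estimated correlation), and Ccl2 had 0.73 and did not pass (adjusted p = 0.0664). In MHC class I presentation 3 of 20 rose and 17 did not pass, with 5 rising adjusted over the list alone (median 0.210; camera adjusted p = 3.07e-05, adjusted p = 0.459 with an estimated correlation). These were the proteasome genes Psme2 (0.68), Psme1 (0.62) and Psmb9 (0.53). No interferon gamma response gene of 13 passed by limma over all genes, 4 rose adjusted over the list alone, and Irf1, Igtp and Irgm2 had 0.79, 0.53 and 0.49. The median of that list was 0.273 (camera adjusted p = 0.00144, adjusted p = 0.459 with an estimated correlation). The cytotoxic T and NK cell list had 3 risers among 9 and 6 that did not pass, with 4 rising and 1 falling adjusted over the list alone (median 0.280; camera adjusted p = 0.0291, adjusted p = 0.448 with an estimated correlation). Gzmc, a granzyme, went from 10.2 ± 2.65 to 52.9 ± 20.7 FPKM (log2 fold change 2.23), and the chemokine Xcl1 and Gzmb rose by 1.63 and 0.96.

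Markers of other cell types differed among the epidermis libraries. The skeletal muscle list had a median of -1.28, with no member of 17 passing by limma over all genes and 9 falling adjusted over the list alone (camera adjusted p = 1.3e-10, adjusted p = 0.465 with an estimated correlation). Myl1, Actn3 and Myh4, genes of the sarcomere, had log2 fold changes of -1.50, -1.43 and -1.42. The mean log2 level of the list was 8.31 and 8.81 in vehicle libraries 1 and 2, 6.67 in vehicle library 3, and 6.79, 6.38 and 6.80 in the CWO libraries. Acta1, skeletal actin, stood at 2786, 4936 and 887 FPKM with vehicle and at 1063, 715 and 781 with CWO. Of 14 fibroblast and dermal matrix genes Col1a1 and Col1a2 fell (-1.28 and -1.18), Postn (periostin) rose by 1.55 and 11 did not pass, among them Col3a1 at -1.26. Adjusted over the list alone 1 rose and 4 fell (median -0.711; camera adjusted p = 0.000482, adjusted p = 0.592 with an estimated correlation). The hair follicle list, which did not pass, had means between 0.995 and 3.94 across the 6 libraries. Vehicle libraries 1 and 2 lay apart on the first principal component of epidermis (50.2% of variance), at -26.0 and -35.3, with vehicle library 3 at 11.8 and the CWO libraries at 15.7, 34.8 and -1.01.

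**Figure D2:**
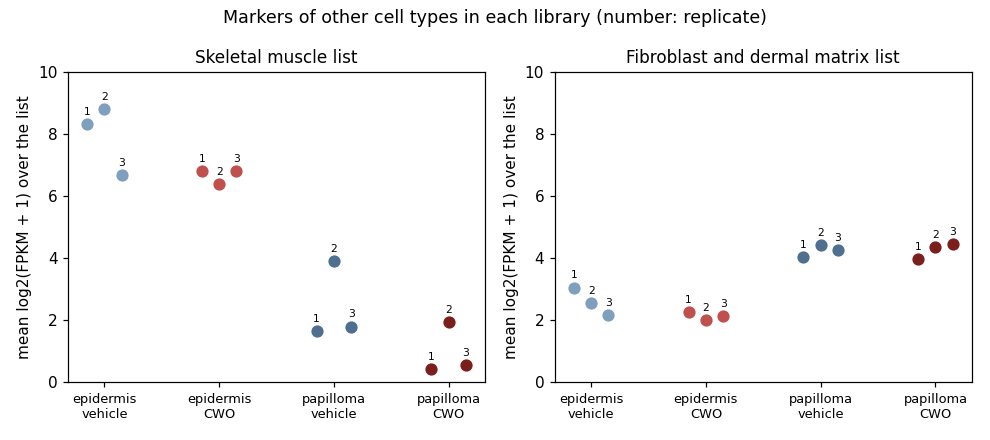
Mean log2(FPKM + 1) over the members (y) of the skeletal muscle list (left) and the fibroblast list (right), 1 point per library with its replicate number, by group (x). Epidermis vehicle libraries 1 and 2 stood at 8.31 and 8.81 on the muscle list and vehicle library 3 at 6.67.

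Of 12290 genes tested by limma in epidermis 245 were called, 223 higher and 22 lower with CWO, and 152 of these changed at least 2-fold. The count was 83, 104 and 675 (363 higher, 312 lower) without vehicle library 1, 2 or 3, and 59 and 92 without CWO library 1 or 2. It was 12 with vehicle library 3 alone kept, a lone library assumed to vary like the CWO group, 15 with the muscle list mean as a covariate, 43 with no filter on low values, 162 by limma-voom and 664 with all 12 libraries in 1 fit. Stfa3, Il1f6 and Pgk1 kept their call in all 22 alternative settings, Sprr2a2 and Chi3l1 lost it in 1, and the other called genes named lost it in 3 to 15. These settings all start from the Cufflinks values, so they do not test how reads were assigned between copies. Of 40 lists tested 14 passed camera, 12 upward and 2 downward, 0 with an estimated correlation and 6 by fry, among them NRF2 oxidative stress genes, which missed camera (fry adjusted p = 0.0388, camera adjusted p = 0.0644). The authors' list for epidermis holds 176 genes, with a highest adjusted p of 0.00544. Of these 175 were tested here, all in the same direction, and 158 were called. Another 87 genes called here at an adjusted p under 0.05 are not in that tighter list.

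**Figure D3:**
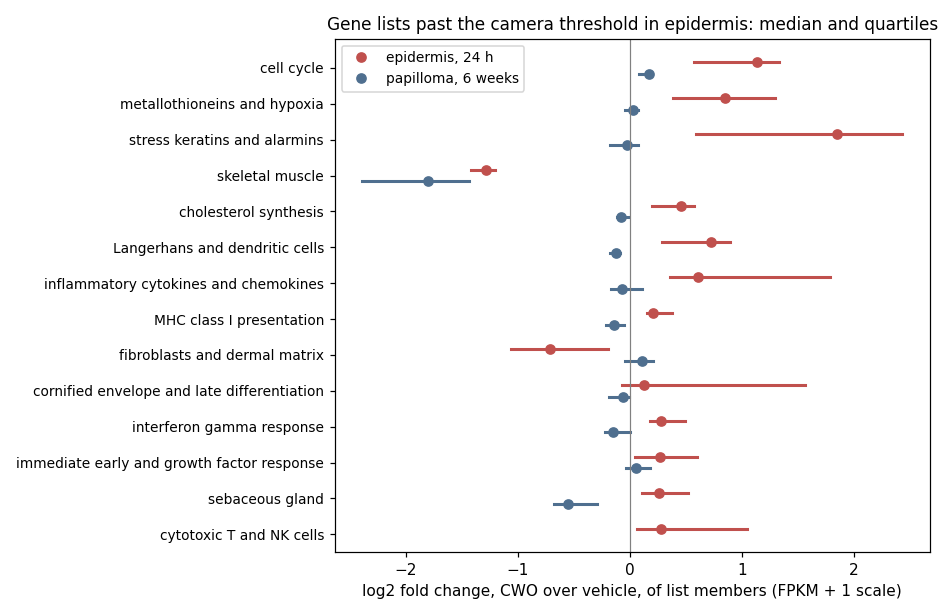
Median (point) and quartiles (bar) of the members' log2 fold change, CWO over vehicle (x), for the 14 lists past camera in epidermis (y), in epidermis and in papilloma. Cell cycle genes had a median of 1.13 in epidermis and 0.168 in papilloma; cytotoxic T and NK cells had fewer than 5 members measured in papilloma and are drawn for epidermis alone.

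A panel of genes was read in both tissues whatever its values. In epidermis Mki67, a proliferation marker, rose by 1.21 on the log2 scale (adjusted p = 0.0309). The keratins Krt16, Krt14, Krt6a and Krt10 had log2 fold changes of 1.85, 0.63, 0.88 and -0.10 and did not pass (adjusted p = 0.0658, 0.174, 0.158 and 0.892). Cd3e, of the T cell receptor complex, had -0.34 (adjusted p = 0.309) and Prf1 (perforin) -0.49 (adjusted p = 0.146). Trpv3, a warmth-sensitive cation channel opened by camphor, had 2.99 ± 0.621 FPKM with vehicle and 3.24 ± 1.83 with CWO (log2 fold change 0.02, adjusted p = 0.992). Cyp1a1, a target of the aryl hydrocarbon receptor, Nqo1, of the oxidative stress response, and Rcan1, a calcineurin regulator, had 0.30, 0.42 and -0.19 and did not pass. Cd8a, Cd4, Ifng, Trpv1, Trpa1 and Trpm8 lay below the filter in both tissues, with at most 34 fragments in any library, and no exact permutation p was under 0.1, the smallest that 3 against 3 libraries allow. Ifng had an exact p of 0.1 in each tissue, at 0.198 ± 0.0848 and 0.336 ± 0.00412 FPKM in epidermis and 0.0556 ± 0.00831 and 0.0160 ± 0.0278 FPKM in papilloma. These values rest on 2 to 6 fragments per library in epidermis and 0 to 1 in papilloma, too few to read a shift in either tissue.

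The second comparison asked what 6 weeks of CWO changed in papillomas. No gene passed: of 12145 tested by limma 0 were called, 306 had an unadjusted p under 0.05 (104 higher, 202 lower), and limma-voom called 0, with 302 under that level. Both numbers lie below the share of 0.05 of tested genes that would reach that level with no effect. Rhcg, an ammonium transporter, had the smallest p, at 5.23 ± 0.569 FPKM with vehicle and 2.11 ± 0.265 with CWO (log2 fold change -1.0, SE 0.115, adjusted p = 0.406). Igfbp6, a binding protein of insulin-like growth factors, and Guca2a (guanylin) had -0.78 and -1.38 (adjusted p = 0.949 for each). Pyy, a gut peptide, Spink12, a protease inhibitor, and Mastl, a mitotic kinase, had 0.87, 0.75 and 0.37 (adjusted p = 1.00 for each). The authors' deposited comparison holds 2 genes with an adjusted p under 0.05, Rhcg (log2 fold change -1.29, adjusted p = 4.14e-05) and 1110012J17Rik (1.33, adjusted p = 0.000309). Both had the same direction here. Among the alternative settings, replicate blocks called Acta1, Ckm, Tnnc2 and Tnnt3, which are muscle genes. A fit of all 12 libraries called Rhcg, which was listed at 0 in every epidermis library, and keeping short genes called Snora75.

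In papilloma 11 of 40 lists passed camera, 4 upward and 7 downward, with no member of any list called by limma over all genes. None passed with an estimated correlation (adjusted p = 0.785 with an estimated correlation for each of the 11) and 0 passed by fry. Every other equal split of the papilloma libraries also moved at least 11 lists by camera. Upward lists were cell cycle (median 0.168, 30 members, camera adjusted p = 5.5e-13), mast cells (0.356, 9, adjusted p = 0.0165), p53 targets (0.0873, 21, adjusted p = 0.0306) and immediate early genes (0.0578, 22, adjusted p = 0.0409). Ccnb1 and Top2a of the cell cycle had log2 fold changes of 0.29 and 0.22, the mast cell proteases Tpsab1 and Cpa3 had 0.56 and 0.70, and the early genes Cyr61 and Nr4a1 had 0.51 and 0.82. Downward lists were skeletal muscle (median -1.80, 11 members, camera adjusted p = 1.54e-10), macrophages and monocytes (-0.226, 19, adjusted p = 3.2e-06) and MHC class I presentation (-0.138, 20, adjusted p = 0.00326). The sebaceous gland (-0.549, 12, adjusted p = 0.0084), the unfolded protein response (-0.123, 20, adjusted p = 0.01), cornified envelope genes (-0.062, 26, adjusted p = 0.0306) and the hair follicle (-0.428, 18, adjusted p = 0.0446) followed. The vehicle libraries were uneven in sebaceous genes. For Scd1, Elovl3 and Far2 vehicle library 2 was highest (139, 27.5 and 15.9 FPKM). Vehicle library 3 (39.5, 5.89 and 3.78 FPKM) lay below every CWO library. For Cidea, Krt79 and Plin2 vehicle library 3 lay within the range of the CWO libraries. Mmp12 and Arg1, enzymes of macrophages, had -0.59 and -0.44, H2-M3 and H2-Q4 had -0.34 each, and Xbp1, a regulator of the unfolded protein response, had -0.25. Adjusted over the list alone 0 genes passed in 10 of these lists and 1 fell among the p53 targets. With median-ratio scaling the cornified envelope, immediate early and hair follicle lists missed the threshold (adjusted p = 0.067, 0.0861 and 0.067). The muscle list had means of 1.65, 3.90 and 1.79 with vehicle and 0.423, 1.94 and 0.547 with CWO, and 18 lists passed without CWO library 1. Of the 11 lists 9, 6 and 7 still passed without vehicle library 1, 2 or 3, and 8, 8 and 7 without CWO library 1, 2 or 3.

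Krt6a and Krt6b, keratins of activated epidermis, could be read in 2 papilloma libraries only, since Cufflinks gave up on their region as too deep in the other 4. Their FPKM were 9169 and 9353 in vehicle library 1 and 9225 and 9732 in CWO library 2. In the authors' deposited table their mean counts were 257980 and 274430 with vehicle and 259650 and 277440 with CWO. In the panel Krt16, Krt14, Krt10, Trpv3, Nqo1, Rcan1 and Mki67 had log2 fold changes of 0.06, 0.10, -0.19, -0.11, 0.19, 0.08 and 0.20 in papilloma, each with an adjusted p of 1.00. Cd3e, Gzmb, Prf1 and Cyp1a1 were below the filter there, with exact permutation p of 0.5, 0.4, 0.3 and 0.3 (n = 3).

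Of 11290 genes tested in both tissues, 208 were higher and 10 lower in epidermis by limma and 0 in papilloma, so overlap could not be tested at that threshold. At an unadjusted p under 0.01, 578 genes were higher in epidermis, 7 in papilloma and 3 in both, against 0.358 expected (Fisher's exact test, two-sided, p = 0.004). With no effect a share of 0.01 of the genes would reach that level, which is more than did so in papilloma. Fisher's test also takes genes as independent, so its p does not show a shared response. The 3, picked out after their values were seen, were Pyy, Mastl and Kifc1, a mitotic kinesin, and Igfbp6 alone was lower in both (69 and 27 genes, 0.165 expected, Fisher's exact p = 0.153). Across genes the 2 sets of log2 fold changes had a Pearson r of 0.0923 and a Spearman rho of 0.0917, and genes are not independent replicates.

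The third comparison tested whether the effect of CWO differed between papilloma and epidermis, which also differ in treatment length, tumour induction and isolation. Of the 94 genes with a downward difference 89 were called higher with CWO in epidermis. The difference was -3.76 for Stfa1, -3.25 for Sprr2a2, -3.06 for Sprr2h and -3.01 for Chi3l1 (log2 scale, SE 0.508, 0.390, 0.463 and 0.408). For Stfa1 in papilloma the authors give mean counts of 541 with vehicle and 162 with CWO (log2 fold change -1.74). Its recovered fragments with vehicle were 1839, 1185 and 1279, and its log2 fold change here was -0.72, so the size of its difference is uncertain. Sprr2a2 stood at 1359 ± 225 FPKM in vehicle papillomas and 1546 ± 243 with CWO (n = 3), although the authors' papilloma table lists it at 0 counts in both groups, so this level is uncertain. Upward differences were found for Rpl34 (3.21), whose reads are shared as above, Hamp (2.96), Cartpt (2.40) and Gng13 (2.27). Of these Hamp, Cartpt and Gng13 had mean log2 levels of 0.12, 0.00 and 0.37 in vehicle papillomas, so that a fall could not be seen there. Of 13187 genes tested by limma 98 differed, 4 higher and 94 lower in papilloma minus epidermis. The count was 62, 64 and 328 (139 higher, 189 lower) without epidermis vehicle library 1, 2 or 3, 34, 56 and 231 without epidermis CWO library 1, 2 or 3, 55 and 57 without papilloma vehicle library 1 or 2, and 46 and 54 without papilloma CWO library 2 or 3. It was 17 with epidermis vehicle library 3 alone kept (assumed to vary like the other groups), 58 by limma-voom and 63 with no filter. Stfa3, Sprr2a2 and Pgk1 kept their call in all 26 alternative settings, and the other called genes that the naming rule picked lost it in 2 to 16. All settings start from the Cufflinks values, so none tests how reads were assigned between copies. For Pgk1 and Idi1 the authors' mean counts in vehicle papillomas were 1215 and 725, against recovered fragments of 6058 to 6680 and 6708 to 9332. Their papilloma log2 fold changes there, -0.03 and -0.13, were near the 0.05 and -0.16 found here.

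Of 42 lists tested for the difference 15 passed camera, 2 upward and 13 downward, 0 with an estimated correlation and 10 by fry. For cell cycle 3 of 30 genes differed and 27 did not pass, 26 adjusted over the list alone (median -0.902; camera adjusted p = 2.35e-24, adjusted p = 0.176 with an estimated correlation). For stress keratins and alarmins 5 of 18 differed and 13 did not pass, 9 adjusted over the list alone (median -1.20; camera adjusted p = 1.56e-10, adjusted p = 0.102 with an estimated correlation). For metallothioneins and hypoxia 4 of 16 differed and 12 did not pass, 12 adjusted over the list alone (median -0.774; camera adjusted p = 6.7e-12, adjusted p = 0.0625 with an estimated correlation). Pgk1, Egln3 and Bnip3, a mitophagy receptor, had differences of -1.49, -1.71 and -1.33. In MHC class I presentation 0 of 20 differed by limma over all genes and 4 adjusted over the list alone (median -0.401; camera adjusted p = 3.64e-08, adjusted p = 0.260 with an estimated correlation). Of its members Psme2, Psmb9 and Psmb8 had -0.67, -0.67 and -0.63 and did not pass.

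The last comparison described vehicle papillomas against vehicle epidermis, the state on which CWO acted. The largest upward differences by the naming rule were in keratin and envelope genes, but the envelope list went both ways. Of its 26 members 15 were higher, 7 lower and 4 did not pass (15 and 7 adjusted over the list alone; median 1.29, quartiles -0.701 and 7.69; camera adjusted p = 0.00355, adjusted p = 0.616 with an estimated correlation). Krt13, a mucosal keratin of squamous tumours, stood at 1376 ± 743 against 0.0247 ± 0.0428 FPKM (log2 difference 10.19), and Lce3b at 1383 ± 337 against 0.487 ± 0.222 (9.85). Lce3a and Sprr2k, at 1214 ± 383 and 749 ± 186 FPKM, were listed at 0 in all 3 epidermis libraries. Lower in papillomas were Hamp2 (-8.71) and the muscle genes Pvalb (-7.59), Myh4 (-7.35) and Ckm (-6.94). The epidermis vehicle libraries hold muscle RNA at the uneven levels given above, and all 16 muscle genes were lower (median -6.08; camera adjusted p = 0.00012, adjusted p = 0.616 with an estimated correlation).

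Of 30 cell cycle genes 29 were higher in papillomas and 1 did not pass, such as Mcm5 at 37.4 ± 1.34 against 10.8 ± 0.743 FPKM (29 adjusted over the list alone; median 1.86; camera adjusted p = 1.58e-09, adjusted p = 0.616 with an estimated correlation). Of 18 stress keratins and alarmins 17 were higher and 1 did not pass (17 adjusted over the list alone; median 6.16; camera adjusted p = 1.74e-09, adjusted p = 0.399 with an estimated correlation). The antiprotease Slpi led with a log2 difference of 8.97, and Stfa3 had 6.84. Of 22 cytokines and chemokines 19 were higher, Tnf alone was lower (-0.36) and 2 did not pass (19 and 1 adjusted over the list alone; median 2.88; camera adjusted p = 1.47e-07, adjusted p = 0.136 with an estimated correlation). Il24 and Il19 had 4.26 and 4.35. Of 23 squamous progression genes 17 were higher, Vim (vimentin) alone was lower (-0.77) and 5 did not pass (18 and 1 adjusted over the list alone; median 1.48; camera adjusted p = 5.81e-06, adjusted p = 0.399 with an estimated correlation).

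Stromal and myeloid lists were higher in papillomas. Of 18 fibroblast and dermal matrix genes 14 were higher and 1 lower (median 2.42, camera adjusted p = 0.00012), of 14 endothelial genes 12 and 0 (1.57, adjusted p = 0.000403) and of 12 neutrophil genes 10 and 1 (2.02, adjusted p = 0.000258). Of 19 macrophage and monocyte genes 13 were higher and 2 lower (1.10, adjusted p = 0.00767), of 9 mast cell genes 7 and 1 (1.64, adjusted p = 0.0152) and of 8 eosinophil and type 2 response genes 6 and 1 (1.68, adjusted p = 0.0173). Of 18 genes of RAS-MAPK output 14 were higher and 2 lower (1.92, adjusted p = 0.000155), of 27 NRF2 genes 16 and 10 (0.857, adjusted p = 0.0152), of 21 p53 targets 13 and 4 (0.673, adjusted p = 0.026) and of 17 basal keratinocyte genes 10 and 3 (1.08, adjusted p = 0.0371). Adjusted over the list alone these counts were equal, apart from 2 lower fibroblast genes, and with an estimated correlation the adjusted p of the 10 lists lay between 0.399 and 0.691.

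Lymphocyte and antigen presentation genes were lower in papillomas. All 14 T cell genes were lower (14 adjusted over the list alone; median -2.16; camera adjusted p = 7.7e-06, adjusted p = 0.399 with an estimated correlation), with Cd3e at 0.828 ± 0.541 against 26.9 ± 4.12 FPKM. Of 8 cytotoxic T and NK cell genes 7 were lower (7 adjusted over the list alone, median -2.72, camera adjusted p = 0.00232, adjusted p = 0.399 with an estimated correlation), and of 5 genes of regulatory and exhausted T cells 4 were lower (4 adjusted over the list alone, median -1.30, camera adjusted p = 0.0481, adjusted p = 0.616 with an estimated correlation). In each 1 gene did not pass. Of 20 MHC class I genes 19 were lower and 1 did not pass (19 lower and 1 higher adjusted over the list alone; median -1.83; camera adjusted p = 2e-06, adjusted p = 0.584 with an estimated correlation). Psmb9, of the immunoproteasome, had -2.59. Of 11 MHC class II genes 10 were lower and 1 did not pass (10 adjusted over the list alone; median -2.12; camera adjusted p = 0.00012, adjusted p = 0.399 with an estimated correlation), with H2-Ab1 at -2.38. All 16 sebaceous gland genes were lower (16 adjusted over the list alone; median -2.83; camera adjusted p = 9.69e-06, adjusted p = 0.616 with an estimated correlation), with Scd3 at -5.87 and Plin2, a lipid droplet protein, at -2.28. In the panel Krt16, Krt14, Mki67, Nqo1 and Trpv3 were higher by 6.44, 2.46, 2.44, 3.35 and 1.67, and Krt10, Prf1, Rcan1 and Cyp1a1 had -1.0, -3.31, -2.13 and -4.40. By limma 8974 of 12791 genes differed, 4070 higher and 4904 lower, and 3848 of them at least 2-fold. Of 42 lists 22 passed camera, 15 upward and 7 downward, 0 with an estimated correlation and 30 by fry. Among genes named for this comparison Tnf lost its call in 12 alternative settings, Krt10 in 2 and Vim in 1. Tissue goes here with tumour induction, isolation and length of vehicle treatment.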

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

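The 2 tests of the normalization here were chosen only after the result was seen; the others were set before. What stood out was a difference between tissues in the effect of CWO, by the interaction test in limma: 98 genes, 4 higher and 94 lower in papilloma minus epidermis. Groups of 3 libraries are too small for a test of single outlying libraries.

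Among envelope and alarmin genes the difference (log2, papilloma minus epidermis) was -3.76 for Stfa1, -3.25 for Sprr2a2, -3.06 for Sprr2h, -3.01 for Chi3l1, -2.83 for Stfa3, -2.67 for Sprr2f and -2.49 for Sprr2d. For cytokines and immune genes it was -2.36 for Il1f6, -2.40 for Ccl20, -1.78 for Ccl22, -2.49 for the granzyme Gzmc, -1.04 for the interferon-induced GTPase Igtp and -1.62 for the macrophage elastase Mmp12. Gzmc lay below the filter in the papilloma comparison, at mean log2 levels of 0.854 with vehicle and 0.589 with CWO. Its difference is therefore mainly its rise in epidermis. Among cell cycle genes it was -1.27 for Ccna2, -1.47 for Birc5 and -1.33 for Aurkb. Hypoxia genes gave -1.49 for Pgk1, -1.71 for Egln3 and -1.33 for Bnip3. Idi1 of cholesterol synthesis gave -0.94 and the matrix gene Postn -1.45. Guca2a gave -2.73, with log2 fold changes of 1.35 in epidermis and -1.38 in papilloma. Rhcg, listed at 0 in every epidermis library, gave -1.0, which is its papilloma change alone. That change did not pass in the papilloma libraries by themselves. The call came from the fit with the epidermis libraries at 0, so it does not show that the effect differs between tissues. Upward differences were 3.21 for Rpl34, whose epidermis reads were assigned between it and the pseudogene Rpl34-ps1, 2.96 for Hamp, 2.40 for Cartpt and 2.27 for Gng13.

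By list, the median difference was -1.20 for stress keratins and alarmins, -0.902 for cell cycle, -0.786 for the cornified envelope, -0.782 for Langerhans and dendritic cells, -0.774 for metallothioneins and hypoxia, and -0.582 for cytotoxic T and NK cells. It was -0.581 for the sebaceous gland, -0.511 for the interferon gamma response, -0.480 for cholesterol synthesis, -0.413 for cytokines and chemokines, and -0.401 for MHC class I presentation. The NRF2 list had -0.230 and squamous progression -0.183. Fibroblasts had 0.575 and mast cells 0.484. Each passed camera at the preset correlation and none with an estimated one.

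A biological candidate is that genes already at the raised level in vehicle papillomas could rise no further: of the 94 genes 57.4% (54) had a higher mean in vehicle papillomas than in epidermis given CWO, against 44.8% of all genes tested, which lies between the bounds set for and against it. Of the 94, 69 were called higher and 12 lower in vehicle papillomas than in vehicle epidermis, so it cannot hold for all. The authors' normalization was excluded as the whole cause of the differences: 84 genes were called under median-ratio scaling and 109 under quantile normalization, and the median size of the 98 differences was 1.39 (quartiles 1.13 and 2.06), then 1.35 (1.07 and 2.00) and 1.32 (1.01 and 2.02), at least 94.9%, all 98 in the same direction. Its share in which genes were called stays open, as at least 74.5% of the 98 kept their call (73 and 78), with 75% asked for; sizes came closer to 0 while the median SE went from 0.236 to 0.229 and 0.221. Treatment length, isolation and tumour induction go with tissue and were not separable.

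Chance was not excluded by regrouping: 9 of 100 drawn splits (of 200 distinct) of treatment within each tissue gave as many genes, with 98 for the real split, which is 1 of the 9, and 155 for the highest other. The other 8 gave 103 to 155, so the real papilloma groups gave the fewest genes of the 9. All 9 keep the real epidermis groups and so carry the epidermis effect, so a share under 0.05 was hardly open to this test. The highest of the 91 that part those groups was 47.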

How the results depend on the processing

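Limma-voom, the muscle covariate, the use of vehicle library 3 alone and values of any status were chosen only after the results were seen; the other settings were set before. The epidermis count of 245 was 43 with no filter, 152 with a 2-fold minimum, 44 with replicate blocks, 664 with all 12 libraries in 1 fit, 162 by limma-voom, 15 with the muscle covariate, 12 with vehicle library 3 alone, and 59 to 675 with 1 library left out. The papilloma count of 0 was 1 with short genes kept (Snora75), 4 with replicate blocks (Acta1, Ckm, Tnnc2 and Tnnt3) and 1 with all 12 libraries (Rhcg), genes named after their values were seen. By limma 306 genes had an unadjusted p under 0.05, below the share of 0.05 that no effect would give, and limma-voom called 0. The interaction count of 98 was 63 with no filter, 25 with replicate blocks, 58 by limma-voom, 17 with vehicle library 3 alone and 34 to 328 with 1 library left out. The tissue count of 8974 was 3848 with a 2-fold minimum. The causes were not tested. A lone vehicle library is assumed to vary like the other groups. With an estimated correlation 0 lists passed in each comparison; by fry 6 passed in epidermis and 0 in papilloma. Papilloma lists ranged from 10 to 18 with 1 library left out, the 18 without CWO library 1, and 6 to 9 of the 11 still passed, the 6 without vehicle library 2. The shared genes were 4 at an unadjusted p under 0.01.

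Replicate numbers were not taken as pairs: deviations of like-numbered libraries from their group means correlated at 0.0244, -0.443 and -0.359 in epidermis and 0.277, 0.139 and 0.0227 in papilloma. Among named genes in epidermis 1084 alternative values kept their side of the threshold, 17 passed it newly and 227 no longer passed; none changed direction while called. For the difference these were 901, 12 and 151, in papilloma 953, 2 and 0, and between tissues 805, 0 and 15. At 11.1 to 24.6 M fragments, genes below the filter carry too few fragments for a firm statement.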

Other observations

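The test of muscle RNA and that of the normalization in epidermis were chosen only after the result was seen; the genes of the next paragraph were also picked after their values were seen. The tests of resemblance and of regrouping were set before.

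The smallest adjusted p in epidermis belonged to 2610528A11Rik, listed under the synonym Gpr15l in the gene table, which rose from 3.15 ± 0.561 to 61.0 ± 11.3 FPKM (log2 fold change 3.89, SE 0.169, adjusted p = 0.000102; higher in all 3 CWO libraries). In papillomas it stood at 901 ± 41.7 FPKM with vehicle and 997 ± 309 with CWO. Defb6, a beta-defensin, rose from 774 ± 51.4 to 2401 ± 173 FPKM, and Aox4, an aldehyde oxidase of skin, from 6.07 ± 0.344 to 29.0 ± 5.31. Ccl17, a chemokine of dendritic cells that shares its receptor with Ccl22, rose by 2.16 on the log2 scale, and Klk6, a kallikrein protease, by 1.83. Fam162a and Ero1l, known as hypoxia-responsive genes outside the fixed list, rose by 1.56 and 1.21, and Tfrc, the transferrin receptor, rose by 1.15. Cldn3, a tight junction claudin, had -0.85, Nkd2, a Wnt inhibitor, -1.19, and Carns1, carnosine synthase, -1.43.

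Genes raised by CWO in epidermis were often also higher in papilloma than in epidermis. Under vehicle 71.0% of 217 raised genes (154) were called higher in papilloma, against 28.5% of 12084 genes, and 43 were lower. That comparison shares its vehicle libraries with the first, and sharing alone correlates them: their r was 0.491, against a mean of 0.581 in 100 simulations with no effect. Their covariance was 5.17 times the highest simulated. The simulations held neither a CWO effect nor a tissue difference, and genes varied independently in them. Neither comparison can therefore decide whether sharing alone gives the resemblance. The argument against sharing alone rests on both tissues given CWO, where shared libraries push the covariance below 0 and it was 0.0935. There 45.3% of 223 raised genes were called higher in papilloma against 25.8% of all, 19.5 percentage points more. Another 80 were called lower, and the share of all genes called lower was not computed. Muscle genes also push this covariance upward. Their list means in epidermis were 8.31, 8.81 and 6.67 with vehicle and 6.79, 6.38 and 6.80 with CWO. In papillomas given CWO they were 0.423, 1.94 and 0.547. How much muscle adds was not tested, so a partly shared response of CWO-treated epidermis and papillomas stays a hypothesis. The level of 2610528A11Rik in papilloma was known before these shares were computed.

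The 245 genes called in epidermis could owe something to skeletal muscle RNA in vehicle libraries 1 and 2, where Acta1 stood at 2786 and 4936 FPKM against 715 to 1063 in the CWO libraries; no gene of that list is in another list. With the muscle list mean as a covariate the median log2 fold change of the 223 raised genes was 0.937 (quartiles 0.724 and 1.32). It was 1.12 (0.831 and 1.43) without the covariate, so 83.5% was kept, and all 223 stayed above 0. These genes had been called from the same libraries, a choice that disfavours genes whose level follows muscle. The test could therefore hardly come out otherwise and does not exclude muscle RNA as a cause. Calls went from 245 to 15, with the median SE at 0.211 against 0.168 and 1 degree of freedom fewer. The shares of these and of the lower fold were not separated. Under median-ratio scaling 217 and under quantile normalization 218 of the 245 genes kept their call, at least 88.6%, which excludes the authors' normalization as the whole cause. An effect of CWO, the biological explanation that the design names, stays open beside a share of muscle or other tissue.

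With 3 libraries against 3 there are 10 splits, too few to exclude chance. For epidermis genes 1 of 10 splits gave as many as the real 245, and the highest other gave 0. For papilloma genes all 10 gave as many as the real 0, and the highest other gave 1. For genes between tissues 1 split gave as many as the real 8974, and the highest other gave 0. For gene lists 3 splits in epidermis gave as many as the real 14, with 22 the highest other. In papilloma 10 did, with 11 for the real split and 20 for the highest other, so treatment moved no more lists there than any regrouping. Between tissues 3 did, with 22 and 31. Why other splits moved more lists than treatment was not tested, and with an estimated correlation 0 lists passed in each comparison.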
